A study of Mus musculus with 29 samples.

How the data were processed

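Hematopoietic stem cells (HSCs) of mouse bone marrow were studied by RNA sequencing in 29 samples of 7 groups. Per the labels, the mice were 8 to 10 weeks old, the treatments lasted 5 days, and 5000 cultured cells were sorted for each sample. RNA was extracted with ISOGEN, copied with a SMARTer Pico kit, amplified by 18 cycles of PCR and sequenced on an Ion Proton instrument, per the labels' protocols and design text. Amplification without molecular identifiers means that reads are not independent molecules.

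The authors deposited 3 tables of reads per transcript, with 9, 12 and 8 sets of library columns. The transcripts carry RefSeq identifiers and the reads were trimmed, per the file headers. The genome build was mm10, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here. The library columns are named by an Ion Xpress barcode and a run number. No label repeats a barcode, so no library column was tied to a sample or a group, and 1 library name stands over more than 1 set of columns. The 203 value columns of the 29 sets were therefore not used, and both wild-type tables were left out.

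The measurements come from 1 column of the STAT1-/- table, which holds the authors' mean read count per transcript over a set of libraries headed S+T, per the file headers. No label explains S+T, so the column was assigned to no treatment. The labels tie the table to STAT1-/- samples, which include untreated cells and cells with IFNg. The mean counts are not scaled for depth or length by the authors, as all of them are multiples of 0.25 and they sum to 35517326 reads. Transcript lengths in bases were taken from the same table, per the file headers. A step of 0.25 is what whole counts averaged over any 4 libraries of the table would give, and a mean over 5 libraries would not keep to it. This number comes from the values and not from a label, so it was used neither as an n nor to choose a treatment group. The mean has no SD here, and the depth of single libraries was not analysed.

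For each of the 29595 transcripts the mean count was divided by the transcript's length and scaled so that all transcripts sum to 1000000, giving TPM. TPM were summed over the transcripts of a gene. Names that differ only in a number added to the symbol (H2-D1_1, H2-D1_2) were treated as copies of 1 gene and summed. With the transcripts of such copies counted in, 4514 of the 21966 genes had several transcripts. A floor of 2 TPM separated genes above it from genes at or under it. Symbols were matched to RefSeq through accessions and synonyms, and coordinates of named genes come from the RefSeq annotation of GRCm38, the assembly that mm10 denotes. The length scaling was tested on 20000 simulated transcripts, where the median error was 2.92% among those with a true level above 2 TPM. The simulated reads followed the model that the scaling inverts. The error therefore reflects the sampling of reads and does not test length bias, read sharing or amplification in these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

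Before the data were examined, 7 comparisons between groups, 30 gene lists and 13 key genes were fixed. None of the 7 comparisons was run, since each needs libraries tied to groups, and the planned tests of the gene lists were left out for the same reason. The planned rule for named genes had parts that rest on those tests and named no gene. Its remaining part, the 13 key genes, was used. All other genes named in the text belong to the fixed lists, apart from Eef1a1, Rps10 and Rps28. The other genes given with a value were chosen as examples after their values were seen. The value of the floor comes from the planned rule, where it only kept low genes from being named. Its use on TPM to count genes, TPM as the measure and its alternatives were chosen after seeing the data. The alternatives were the mean count scaled to the same sum with no length scaling (RPM), the transcript with most reads alone, summed reads over the longest transcript, the copy with most reads alone, and floors of 1 and 5 TPM. Mx1, Mx2, Cxcl11, Ighm, Tpsab1 and the 13 mitochondrially encoded genes of the lists had no row under their symbols or synonyms and were not analysed here. Lnk and Sh2b3, names of the same gene in the list of thrombopoietin and STAT5 targets, were counted as 1 gene.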

Results

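The series profiled mRNA of cultured HSCs, the cells that renew themselves and give rise to all blood lineages. The cells were exposed for 5 days to interferon gamma (IFNg), a cytokine that signals through the transcription factor STAT1, to vitronectin (VN), an extracellular matrix protein bound by integrins, or to both. Wild-type C57BL/6 cells made up 4 samples each of a control for VN, VN, a control for IFNg, IFNg, and IFNg with VN. Cells of STAT1-/- mice, on a mixed C57BL/6 and 129Sv background, made up 4 control samples and 5 samples with IFNg. The design implies 7 comparisons. They ask what IFNg changes in wild-type cells, what VN adds to IFNg, what VN changes alone, what IFNg changes without STAT1, and whether these effects differ between genotypes or with IFNg. None could be made here, because no library column could be tied to a sample, and no fold change or test is reported. The values below are levels in the authors' mean of the libraries headed S+T in the STAT1-/- table, whose treatment the labels do not give. They are therefore described as levels of STAT1-/- cells, with no treatment named. The single libraries behind the mean were not used, so no spread is given and differences between genes were not tested.

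The S+T mean summed to 35517326 reads over 21966 genes. Of these genes, 10361 (47.2%) lay above 2 TPM with a median of 25.3 TPM, 7826 lay above 0 and at or under 2 TPM, and 3779 were listed at 0. Eef1a1, a translation elongation factor and the gene with the highest TPM, took 1.10% of the reads. The 20 genes with most reads took 6.85%.

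Stat1, the gene targeted in these mice (chromosome 1, 52119438 to 52161865, GRCm38), had a mean of 1454.5 reads and 13.3 TPM, or 41.0 RPM without length scaling. Its 3 annotated transcripts, of 5168, 5153 and 5135 bases, held 87.4%, 9.50% and 3.13% of these reads. How reads that match more than 1 of them were counted is not known, so these shares do not show which transcript was used. Counts over whole transcripts do not show whether the deleted part was transcribed, so this level checks nothing about the genotype. Of 18 genes of IFNg signalling and feedback, 16 lay above 2 TPM, with a median of 12.6 TPM. Both chains of the IFNg receptor were among them, Ifngr1 at 74.9 TPM (chromosome 10, 19591949 to 19610229) and Ifngr2 at 41.5 TPM (chromosome 16, 91547059 to 91564007). The receptor-associated kinases Jak1 and Jak2 stood at 120 and 24.7 TPM. Irf1, a transcription factor induced by IFNg, stood at 28.9 TPM (chromosome 11, 53770014 to 53778374) and Socs1, an inhibitor of the pathway, at 10.1 TPM (chromosome 16, 10783808 to 10785536). Ciita, the activator of MHC class II genes, stood at 0.124 TPM.

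Interferon-inducible genes were described by list. Of 20 IFNg-inducible GTPases, 11 lay above 2 TPM, with a median of 3.38 TPM. Irgm1 reached 55.4, Ifi47 45.0 and Gbp7 31.7 TPM, whereas Gbp4 stood at 0.00264 TPM on a mean of 0.25 reads. Of 20 genes of MHC class I and antigen processing, 18 lay above 2 TPM, with a median of 63.3 TPM. B2m, the invariant light chain, reached 1474 TPM, the heavy chain gene H2-D1 837 TPM and the immunoproteasome subunit gene Psmb8 269 TPM. MHC class II genes had a median of 2.22 TPM, and 6 of 11 lay above 2 TPM. H2-DMa, whose product helps to load peptides, stood at 64.1 TPM, while H2-Ab1, H2-Aa and H2-Eb1, which encode chains of the presenting molecules, stood at 2.22, 0.686 and 0.163 TPM. Among 30 type I interferon-stimulated genes, 19 lay above 2 TPM and the median was 4.18 TPM. Bst2 was at 130 and Ifi35 at 48.4 TPM, compared with 0.166 TPM for Ifit1 and 0.725 TPM for Rsad2. Chemokine and cytokine genes had 7 of 17 members above 2 TPM and a median of 0.711 TPM, with Cxcl9 at 0.0122 and Cxcl10 at 0.150 TPM. Of 16 immune checkpoint and surface genes, 10 lay above 2 TPM, with a median of 7.49 TPM. Cd274, which encodes the ligand PD-L1, stood at 14.5 TPM (chromosome 19, 29362107 to 29388095), or 31.3 RPM without length scaling. Reads of gene families with near-identical members, such as Gbp, Tgtp, Ifitm and MHC genes, may be split between members, and their single values are uncertain. Reads listed under several numbered copies were summed, among them those of H2-D1, Psmb8, H2-DMa, H2-Ab1, H2-Aa, H2-Eb1, Irgm1, Ifi47, Igtp, Pf4 and Cdkn1a. With the copy with most reads alone, 5 MHC class II genes lay above 2 TPM.

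**Figure D1:**
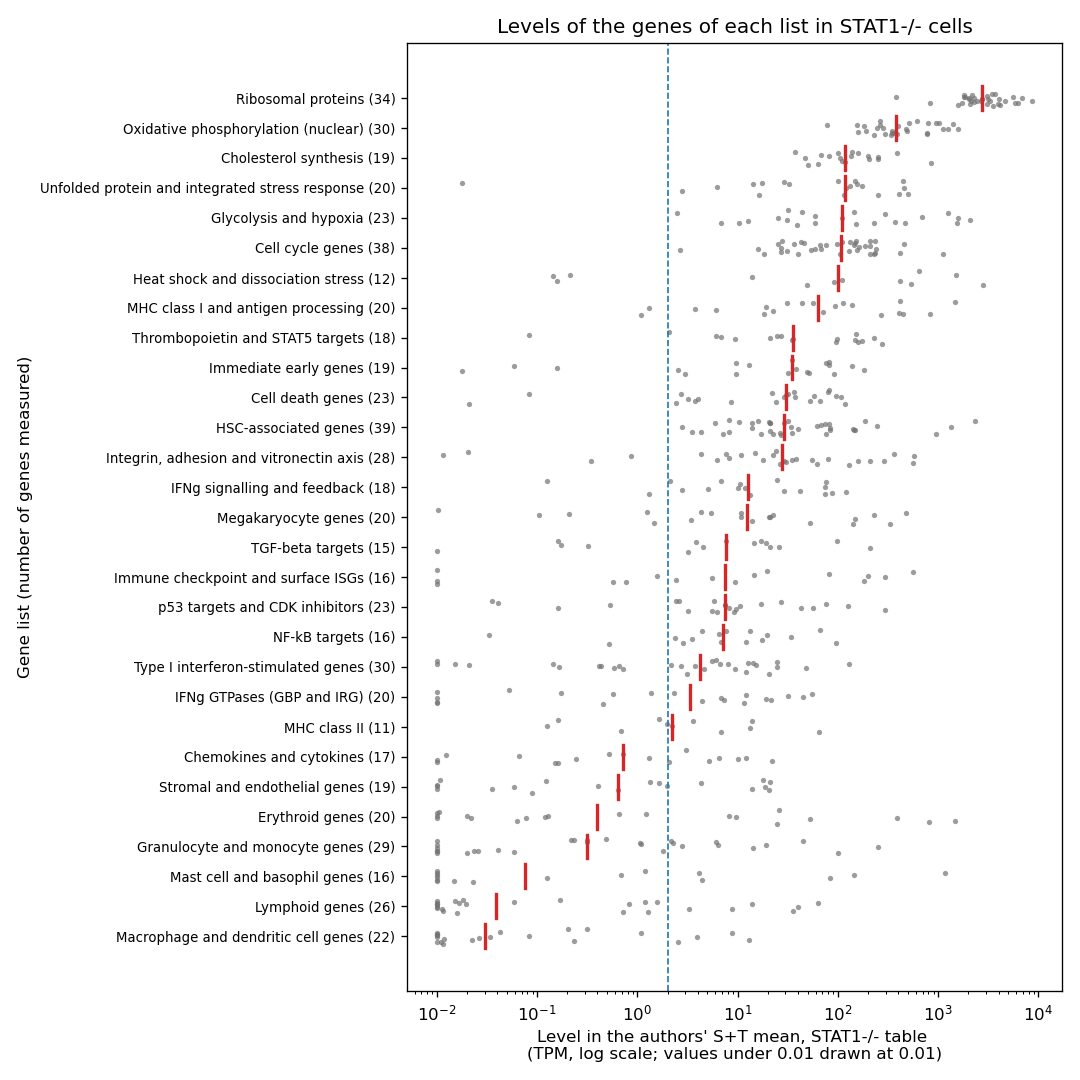
Levels of the genes of each fixed list in the authors' S+T mean of the STAT1-/- table, in TPM on a log axis, with 1 point per gene, a red bar at the list's median and a dashed line at 2 TPM. Values under 0.01 TPM are drawn at 0.01, and list medians run from 0.0301 TPM for macrophage and dendritic cell genes to 2715 TPM for ribosomal proteins.

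All 39 HSC-associated genes lay above 2 TPM, with a median of 29.0 TPM. Mecom, a transcription factor gene needed for HSC maintenance, stood at 62.5 TPM (chromosome 3, 29951296 to 30509759), or 134.6 RPM without length scaling. Mpl, which encodes the thrombopoietin receptor, stood at 147 TPM (chromosome 4, 118442412 to 118457688). Its level was 88.6 TPM with the transcript with most reads taken alone, and 256 RPM without length scaling. Meis1 stood at 187, Kit at 145, Procr at 82.6 and Hlf at 74.1 TPM. Genes of mature lineages were lower on the median. Of 29 granulocyte and monocyte genes, 10 lay above 2 TPM and the median was 0.315 TPM. Mpo and Elane, which encode neutrophil granule proteins, stood at 0.311 and 0.0257 TPM, while the lysozyme gene Lyz2 stood at 250 and the transcription factor gene Spi1 at 100.1 TPM. Erythroid genes had 8 of 20 members above 2 TPM and a median of 0.391 TPM, with Car2 at 1464, Nfe2 at 385 and Gata1 at 1.22 TPM. Megakaryocyte genes had 15 of 20 above 2 TPM and a median of 12.3 TPM, led by Cd9 at 473 and Pf4 at 330 TPM, and 4 of these 15 also belong to the HSC list. Lymphoid genes had 6 of 26 above 2 TPM and a median of 0.0390 TPM. Ikzf1 stood at 63.6, Nkg7 at 40.1, Cd79b at 35.5 and Lck at 13.9 TPM, compared with 0.0113 TPM for Dntt and 0.00355 TPM for Rag1.

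Lists of other cell types that a culture of marrow cells could hold were also low on the median. Mast cell and basophil genes had a median of 0.0749 TPM, with 5 of 16 above 2 TPM. These were Srgn, Kit, Gata2, Fcer1a and Il4, of which Kit and Gata2 are also in the HSC list. The mast cell protease genes Cma1, Mcpt4 and Tpsb2 were listed at 0. Macrophage and dendritic cell genes had a median of 0.0301 TPM, with 4 of 22 above 2 TPM, namely Cd68, Flt3, Zbtb46 and Cd14. The stromal and endothelial genes had a median of 0.648 TPM and 6 of 19 above 2 TPM, of which Tek and Vwf are also in the HSC list. Without length scaling, 10 of these 19 lay above 2 RPM. With a floor of 5 TPM, 3 mast cell and basophil genes and 2 macrophage and dendritic cell genes lay above it.

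All 38 cell cycle genes lay above 2 TPM, with a median of 107 TPM. Mki67, a marker of cycling cells, stood at 43.1 TPM (chromosome 7, 135689784 to 135716450), or 258 RPM without length scaling. Pcna stood at 458 and Top2a at 146 TPM. Of 23 p53 targets and cyclin-dependent kinase inhibitors, 19 lay above 2 TPM, with a median of 7.49 TPM. Cdkn1a, a p53 target that halts the cell cycle, stood at 27.3 TPM (chromosome 17, 29090979 to 29100722) and Cdkn1c, which encodes another inhibitor, at 17.2 TPM (chromosome 7, 143458339 to 143461059). The level of Cdkn1a was 15.2 TPM with the transcript with most reads taken alone. Of 23 cell death genes, 21 lay above 2 TPM, with a median of 30.5 TPM. Among them, Ripk3 stood at 118 and Casp8 at 108 TPM.

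Itgav and Itgb3 encode a pair of integrin chains that form a receptor of vitronectin, which is not the only integrin that binds it. Itgav stood at 6.19 TPM (chromosome 2, 83722303 to 83806917), or 26.0 RPM without length scaling. Itgb3 stood at 4.32 TPM (chromosome 11, 104608000 to 104670476), or 14.9 RPM. Of 28 genes of the integrin, adhesion and vitronectin list, 24 lay above 2 TPM, with a median of 27.9 TPM. The integrin chain gene Itgb1 stood at 129 TPM, and Vtn, which encodes vitronectin itself, at 0.0203 TPM. Thrombopoietin and STAT5 targets had 17 of 18 members above 2 TPM and a median of 35.3 TPM, with Pim2 at 278, Socs2 at 229 and Myc at 174 TPM. The TGF-beta targets had 11 of 15 above 2 TPM and a median of 7.60 TPM. NF-kB targets had 14 of 16 above 2 TPM and a median of 7.22 TPM, and immediate early genes 16 of 19 and a median of 34.8 TPM.

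All 34 ribosomal protein genes of the fixed list lay above 2 TPM, with a median of 2715 TPM, and together took 5.26% of the reads. The list leaves out some ribosomal protein genes, such as Rps10 and Rps28, so this is not the share of the whole family. Their many pseudogenes make single values uncertain. All 30 nuclear genes of oxidative phosphorylation, all 23 of glycolysis and hypoxia and all 19 of cholesterol synthesis also lay above 2 TPM. Their medians were 376, 110 and 118 TPM. In the unfolded protein and integrated stress response list 19 of 20 lay above 2 TPM, with a median of 117 TPM. Of 12 genes of heat shock and dissociation stress, 9 lay above 2 TPM, with a median of 100.4 TPM. Hspa8 stood at 2775 TPM, while the inducible genes Hspa1a and Hspa1b stood at 0.212 and 0.143 TPM.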

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

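All settings reported here were chosen after seeing the data. The settings fixed at the outset, which include leaving out each replicate in turn, belong to the comparisons between groups and could not be run without libraries tied to groups. No paired analysis was possible because no column of the tables carries a sample or replicate number. Counts of genes above the floor were recomputed under 6 settings, and 177 of 180 counts stayed within 1.5 times the reported one. Lists with all members above the floor could not rise and seldom could move that far, so this number says little about them. The list medians were not recomputed. With a floor of 5 TPM, the mast cell and basophil genes above it went from 5 to 3 and the macrophage and dendritic cell genes from 4 to 2, by construction of the higher floor. With RPM and no length scaling, the stromal and endothelial genes above 2 RPM went from 6 to 10. RPM and TPM come from the same reads and differ only in the length scaling, so this change follows from it. Over all genes, the count of 10361 ranged from 9152 to 11012. Spearman's rho across genes against the reported levels was 0.983 with no length scaling, 0.998 with the transcript with most reads and 0.999 or more with the longest transcript and with the copy with most reads. Only 4514 of the 21966 genes have several transcripts, those of copies counted in, and 933 have numbered copies. A high rho for the settings on transcripts and copies was therefore largely fixed in advance. No rho applies to the floors. A rank correlation over all genes does not show how far single levels moved. With the transcript with most reads alone, Irf1 went from 28.9 to 20.6 TPM and Mecom from 62.5 to 50.2 TPM. Ifngr1 has 1 transcript, so this setting left its reads as they were, yet its level went from 74.9 to 79.3 TPM. Such a rise reflects the rescaling of the kept transcripts to the same sum and not the choice of a transcript. The same rescaling is part of the levels of Irf1, Mecom, Mpl and Cdkn1a under this setting, so their falls before it were larger. Genes are not independent replicates. Depth per library was not analysed, so a level near the floor has no interval here.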

Other observations

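All tests in this part were chosen after the values they rest on were seen.

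The globin genes differed in level in the S+T mean. The beta-globin gene listed as Hbb-b1 stood at 808 TPM on a mean of 10690 reads, and another beta-globin gene, Beta-s, at 9.53 TPM. The alpha-globin genes Hba-a1 and Hba-a2 stood at 0.127 and 0.0630 TPM, and Alas2, the first enzyme of heme synthesis in erythroid cells, at 0.121 TPM. Globin genes have near-identical copies, so single values are uncertain. Among serine protease genes of neutrophil granules, Prtn3 stood at 44.7 TPM, against 0.0257 TPM for Elane and 0.0236 TPM for Ctsg. These are values without an explanation.

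The table lists 933 genes in several numbered copies, which hold 4.21% of the reads and include 49 genes of the fixed lists. Such copies are known from the numbered names alone, so they do not show that the genome carries a gene several times. Of the 433 with a mean of 100 reads or more, 136 had their largest copy within 5 percentage points of an even split, 81 had 90% or more in 1 copy and 216 lay in between. The reads of H2-D1 were spread over 4 copies at 25.1%, 24.7%, 25.2% and 25.0%, whereas Cdkn1a had 95.2% in 1 copy and 4.80% in the other. Some genes in between were even within pairs of copies, such as H2-K1 at 50.1%, 49.8% and 0.0802% and Psmb8 at 35.6%, 35.5%, 14.3% and 14.6%. The share near an even split over all copies leaves such genes out.

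A candidate explanation for these splits is that reads of identical copies were shared between them. The first test asked how many of the 433 genes were near even. The share was 31.4%, which lay between the bounds of 10% and 90% set for it and left the explanation open. A narrower test was added once both shares were known, with a bound of 5% on genes that have 90% or more of their reads in 1 copy. That share was 18.7%, which restates the count of 81 genes and shows no more than that the reads of these genes were not split evenly. Uneven sharing between copies that differ in part was not tested, so sharing stays open for all 433 genes. No biological explanation was tested.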
